A study of Glycine max with 5 samples.

How the data were processed

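Single-nucleus RNA was measured in 5 soybean libraries, 3 from roots at 6 days and 2 from nodules at 32 days. The deposited values were raw UMI counts (counts of unique molecular identifiers) per feature and barcode, with every barcode listed and no filter on barcodes. The matrices came from Cell Ranger, which stands as version 6.1.1, beside Seurat, in the submitters' processing notes, while the counts carry a version 4 software line per the file headers. The genome build and annotation were not given in the sources used here, so no coordinates are printed. All 5 matrices held the same 57147 features, of which 108 protein-coding ones carried a name. Gene names are those paired with the identifiers in the feature tables. No columns of other series were in the tables.

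A barcode was taken as a nucleus when its UMI count reached the larger of 500 and the 99th percentile of the top 3000 barcodes divided by 10. These minima were 816, 1033 and 1434 UMIs in root libraries 1 to 3 and 736 and 1447 in nodule libraries 1 and 2. Scrublet, with an expected doublet share of 6%, marked 1 barcode in root 1, 1 in root 2, 0 in root 3, 1 in nodule 1 and 0 in nodule 2. At that number the caller has not worked, so doublets were in effect kept. Free RNA was described by the plateau barcodes, ranked 10000 to 50000 by UMI count, and empty droplets by the barcodes of 1 to 50 UMIs. The free RNA subtraction at 10% used the profile of the empty droplets, and the plateau-level subtraction that of the plateau. These profiles differed. LBA in nodule libraries 1 and 2 stood at 21560 and 24940 CPM in plateau barcodes, against 10710 and 11610 in empty droplets. In nodule 1 the barcode at rank 10000 had 748 UMIs, above the minimum of 736. Some barcodes there were thus both nuclei and plateau.

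For the comparison of tissues, counts were summed over the nuclei of each library, because nuclei are not replicates. The sums were scaled by TMM, filtered by filterByExpr and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values of the tissue comparison use the TMM-scaled library sizes, and CPM values of clusters and barcode classes use plain totals. Where a tissue had no count, the fold is a bound against a floor of 3 counts over the group; with 1 to 3 counts, the ratio carries a 95% counting interval. Intervals and floors cover counting error only. On simulated counts for the 34681 genes tested, 50 genes were changed per fold size, 200 in all. The test recovered 0% of 1.5-fold, 0% of 2-fold, 22% of 4-fold and 62% of 8-fold changes. It called 3 unchanged genes and gave 0 calls in the wrong direction. In the data 15153 genes passed, so the adjusted threshold was easier to reach there, and these recoveries do not carry over.

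Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest named genes past the threshold with at least 50 CPM in the higher tissue and all libraries of one tissue above all of the other, the 3 most abundant tested members of each list, all leghemoglobins, the identifiers fixed in the lists, and a pair of unnamed identifiers each way. The design's lists rest on gene descriptions that were not used here, so only the leghemoglobins and the Nod factor signalling identifiers stand as fixed before the data were examined. The other 8 of the 10 lists were built after the feature names were read and before any count per gene was looked at. They are carbon and nitrogen metabolism of nodules, phenylpropanoid and isoflavonoid synthesis, phytoalexin and defence, small heat shock proteins, seed and vegetative storage, lipid synthesis, named plastid-type genes, and ribosomal protein and ubiquitin. Lists of at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with camera at an estimated correlation and with fry beside it. The fry p asks whether a list's genes move, on balance, one way, and compares the list with no other genes.

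Nuclei of each tissue were clustered separately (scanpy 1.11.5, igraph 0.11.9): scaling to 10000 counts per nucleus, 2000 highly variable genes, standardisation within each library with values clipped at 10, 30 principal components, 15 neighbours and Leiden resolution 0.5, with 1 thread and random seed 0. A nodule cluster was called infected-like from the 5 infected-cell markers fixed before the data were examined. The scoring rule was chosen after seeing the data: in each library with at least 10 nuclei of the cluster, at least 3 of the 4 markers beside LBA had to stand 1.2 times above the level that LBA and the plateau's proportions give, with a one-sided binomial p under 0.01. A stricter version, which asks for 10 nuclei in every nodule library, was tried after the result of the first was seen. The first version was put back after both had been seen, and the stricter one is kept as an alternative. On simulated clusters the rule named 0 of 20 made of free RNA and 20 of 20 with 4 markers raised. The first were drawn at the plateau's proportions and the second beyond the rule's own bound, so this checks the code only. It does not show that the rule finds infected cells in real clusters. The partition was found to depend on rounding when a repeat without a fixed thread number gave other clusters, so 20 other random seeds were run.

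Alternatives covered the scaling, DESeq2 1.42.0, the low-count filter, the UMI minimum, all barcodes, doublets, free RNA, depth, leghemoglobins, a replicate block, each library left out, the clustering settings, the random seeds and the naming rule. No class was named in both tissues, so shares between tissues, the tissue effect within a class and its difference between classes were not analysed here.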

Results

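RNA was measured in single nuclei of soybean seedling roots and of root nodules from plants inoculated with rhizobia, the organs in which rhizobia fix nitrogen. The data comprised 3 root libraries at 6 days and 2 nodule libraries at 32 days. The root libraries held 14665336, 20727649 and 31599717 UMIs, and the nodule libraries 47501352 and 48565100. Root libraries 1 to 3 gave 4201, 3470 and 4625 nuclei, with median UMI counts of 1404, 1660 and 2961. Nodule library 1 gave 10409 nuclei with a median of 992 UMIs, and nodule library 2 gave 2795 nuclei with a median of 2100. Plateau barcodes, taken here as free RNA, had median counts of 66, 143 and 237 UMIs in the root libraries. In the nodule libraries they had 552 and 518, or 55.6% and 24.7% of a median nucleus. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was at least 19.98, the value of the nodule pair.

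The first comparison asked which genes differ between nodule and root nuclei. Leghemoglobins, the oxygen-binding proteins of infected nodule cells, included the gene with the highest fold between the tissues. LBA (GLYMA_10G199100) was counted 0 times in the 3 root libraries and reached 14140 ± 5540 CPM (SD, n = 2) in nodules, at least 175000-fold higher. In plain totals LBA held 14150 and 8438 CPM in nuclei of nodule libraries 1 and 2, against 21560 and 24940 in plateau barcodes. Its level in nuclei was thus not separated from free RNA. Nodulin GMN16, sucrose synthase SS and phosphoenolpyruvate carboxylase PPC1 were also higher in nodules, while the allantoate amidohydrolases AAH1 and AAH2 were lower. CYP93A1 of glyceollin synthesis, chalcone isomerase CHI1A and isoflavone synthase IFS2 were lower in nodules, although other genes of their lists did not fall.

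Of 34681 genes tested, 7503 were higher and 7650 lower in nodules by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The difference reached 1 on the log2 scale for 7233 of the higher and 7434 of the lower genes. The median log2 fold change of all tested genes was -0.07. Among genes of at least 50 CPM in both tissues, 482 of 2339 passed the threshold. There were 102 genes with 0 counts in root and at least 50 CPM in nodule, and 6 the other way. Without nodule library 1 the total of 15153 calls dropped to 7638, and without nodule library 2 to 8009. Nothing says that the libraries came from separate plants, so the p-values measure the spread between these samples, which may be technical; tissue, age and inoculation changed together.

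All 4 leghemoglobins rose, by the count over all genes and by the count adjusted over the list alone. LGB1 (GLYMA_10G198800) stood at 5259 ± 151 CPM in nodules (SD, n = 2), at least 64900-fold above root. GLYMA_10G199000 was at least 79900-fold and GLYMA_20G191200 at least 49700-fold higher. The list's median log2 fold change was 18.96 as fitted and 16.14 with the genes at their bound. Its camera adjusted p was 1.06e-05, and the adjusted p was 0.558 with an estimated correlation. Leghemoglobins took 2.80% and 1.99% of the UMIs of nodule nuclei in libraries 1 and 2, against 4.14% and 5.29% in plateau barcodes. Reads of these near-identical copies may not be told apart in the counting, so the level of each copy is uncertain. The unnamed genes GLYMA_13G364400 and GLYMA_14G052400 were also at 0 counts in root and at least 163000-fold and 101000-fold higher in nodules. GLYMA_04G049200 and GLYMA_05G103700 had 0 counts in nodule and were at least 1440-fold and 1070-fold lower there, a call that the second lost without either nodule library. The second stood at 4.98, 495.3 and 45.9 CPM in root libraries 1 to 3, and without root library 2 its bound was 150-fold.

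Of the 13 tested identifiers of the Nod factor signalling list, 6 rose and 2 fell over all genes tested. The list holds receptors and later regulators of nodulation together, so these counts do not speak for the recognition of rhizobia alone. Adjusted over the list alone, 6 rose and 3 fell. GLYMA_02G311000 rose from 1.15 ± 0.798 CPM in root (SD, n = 3) to 135.5 ± 29.4 in nodule (SD, n = 2), a log2 fold change of 6.81. GLYMA_04G000600 rose by 6.60 on the log2 scale, to 302.9 ± 52.9 CPM (SD, n = 2). GLYMA_06G000400 had 3 counts over the root libraries, and its nodule to root ratio was 1600 (95% counting interval 547 to 7760). GLYMA_14G046200 had 1 count over the nodule libraries, and its root to nodule ratio was 119 (21.2 to 4720). The other that fell over all genes, GLYMA_11G063100, had 2 counts over the nodule libraries and a ratio of 9.81 (2.55 to 83.7), and lost its call without either nodule library, with DESeq2, with no filter beyond 1 count and with the plateau-level subtraction. The camera adjusted p of the list was 0.135, and the adjusted p was 0.558 with an estimated correlation. Over the camera fits of the list under other settings the adjusted p ran from 0.0296 to 0.558, and it passed the threshold under some of them, for example with free RNA subtracted at 10% (0.0388) and without root library 1 (0.0452).

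In carbon and nitrogen metabolism of nodules, 5 of 9 genes rose and 3 fell. GMN16 (GLYMA_02G265200), a nodulin, had 1 count over the root libraries and 1771 ± 347 CPM in nodules (SD, n = 2), a ratio of 64000 (95% counting interval 11500 to 2530000). PPC1 (GLYMA_12G229400), which fixes carbon into oxaloacetate, rose from 35.9 ± 4.13 (SD, n = 3) to 297.5 ± 70 CPM (SD, n = 2), a log2 fold change of 3.05. Its relative PPC16 fell by 0.90 on the log2 scale, a call lost, among others, without root library 2 or 3 or either nodule library. SS (GLYMA_13G114000), which cleaves sucrose, rose by 2.13, and the catalases CAT2 and CAT4 by 2.25 and 1.76; CAT4 lost its call without nodule library 1. The allantoate amidohydrolase AAH2 fell by 2.26 on the log2 scale, and AAH1 was lower with a root to nodule ratio of 89.0 (24.5 to 737). The camera adjusted p of the list was 0.211.

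In phenylpropanoid and isoflavonoid synthesis, 2 of 10 tested genes rose and 4 fell. CHI1A (GLYMA_20G241500), a chalcone isomerase, dropped from 73.3 ± 3.57 (SD, n = 3) to 14.8 ± 0.633 CPM (SD, n = 2), a log2 fold change of -2.31. The isoflavone synthase IFS2 fell by 3.10 on the log2 scale, and cinnamate 4-hydroxylase CYP73A11 by 1.85, a call lost without either nodule library. CYP98A2 rose by 2.25, a call lost without root library 2 or either nodule library. The other that rose, GmIF7GT1, by 2.23, lost its call, among others, without either nodule library, after thinning and with free RNA subtracted at 10%. The chalcone synthases can share reads, so CHS6, with 1 count in nodule and a root to nodule ratio of 34.9 (6.07 to 1400), is uncertain, and its call was lost without nodule library 2. The camera adjusted p of the list was 0.507.

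In phytoalexin and defence, 1 of 10 tested genes rose and 5 fell. CYP93A1 (GLYMA_03G143700), of glyceollin synthesis, dropped from 285.8 ± 73.7 (SD, n = 3) to 39.5 ± 11.3 CPM (SD, n = 2), a log2 fold change of -2.85. The glyceollin prenyltransferase G4DT fell by 2.42 on the log2 scale, a call lost without either nodule library. CYP82A2 fell by 1.40, a call lost when any of root libraries 1 and 2 and the nodule libraries was left out. PR10 had 0 counts in nodule and was at least 12.5-fold lower there, a call lost without either nodule library and with free RNA subtracted at 10%, where its fitted log2 fold change was -7.37 against -7.50. Without root library 2 its bound was 5.62-fold. PRP3 had 3 counts in nodule, with a 95% counting interval of 5.85 to 86.4 for its root to nodule ratio, and its log2 fold change was -3.86, but -2.71 and not called without nodule library 1, and 0.69 in sums over every barcode. CYP71A9 rose by 3.07 on the log2 scale, a call lost without nodule library 1, and stood at 0.05 (adjusted p = 0.965, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) with free RNA subtracted at the plateau level. The camera adjusted p of the list was 0.200. Outside the lists, the cytochrome P450 CYP93A2 fell by 4.57, PNC1 rose by 3.71 and the UDP-glucose dehydrogenase UGD1 by 3.15. IDH1 fell by 1.31 and TBP1 by 0.96, calls lost without either nodule library, with a minimum of 500 UMIs and with sums over every barcode, and for TBP1 among others without root library 2.

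Markers of RNA from outside the nucleus moved with the tissue too. All 8 tested plastid-type genes rose, with petA at a log2 fold change of 4.20 and rpl33 at 3.96 (camera adjusted p = 0.0011, and adjusted p = 0.558 with an estimated correlation). Without nodule library 1 the calls of psaJ, psbN, psbM and rpl23-A were lost, and without nodule library 2 that of psaJ. With free RNA subtracted at 10%, psbM lost its call at a log2 fold change of 1.92 against 3.07, and rpl23-A at 3.28 against 3.03, so its fold was no smaller there, but it was 1.90 and not called with the plateau-level subtraction. With the doubled UMI minimum psbM was not called either. In the ribosomal protein and ubiquitin list 6 of 9 genes rose (camera adjusted p = 0.00927, and adjusted p = 0.558 with an estimated correlation). TCTP, by name neither a ribosomal protein nor a ubiquitin, rose by 3.60, and the RPS13 copy GLYMA_05G052300 by 2.14. Copies of RPS13 and SUBI-1 can share reads. Without either nodule library the RPS13 copies GLYMA_05G052400 and GLYMA_17G134800 lost their calls, the first also, among others, after thinning and with free RNA subtracted at 10%. Of 83 tested ribosomal RNA features 11 were lower, 0 were higher and the rest did not pass the threshold. In lipid synthesis 2 of 6 tested genes rose and 1 fell (camera adjusted p = 0.507). Of these, DGAT1C, at a log2 fold change of 1.01, lost its call without nodule library 2 (0.52) and without any 1 of the root libraries. With all libraries it also lost its call with a minimum of 500 UMIs (0.42) and over every barcode (0.44). DGAT1B, at -1.12, lost its call without either nodule library. The small heat shock genes HSP26-A and HSP17.5-E had log2 fold changes of 0.48 and -3.28, and the second passed the threshold, a call lost without either nodule library and with the doubled UMI minimum. Of 3 tested storage genes 1 rose and 1 fell (camera adjusted p = 0.929). The one that rose, glycinin GY1, held 5.66 and 3.49 CPM of plain totals in nodule nuclei against 11190 and 10280 CPM in nodule barcodes of 1 to 50 UMIs.

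**Figure D1:**
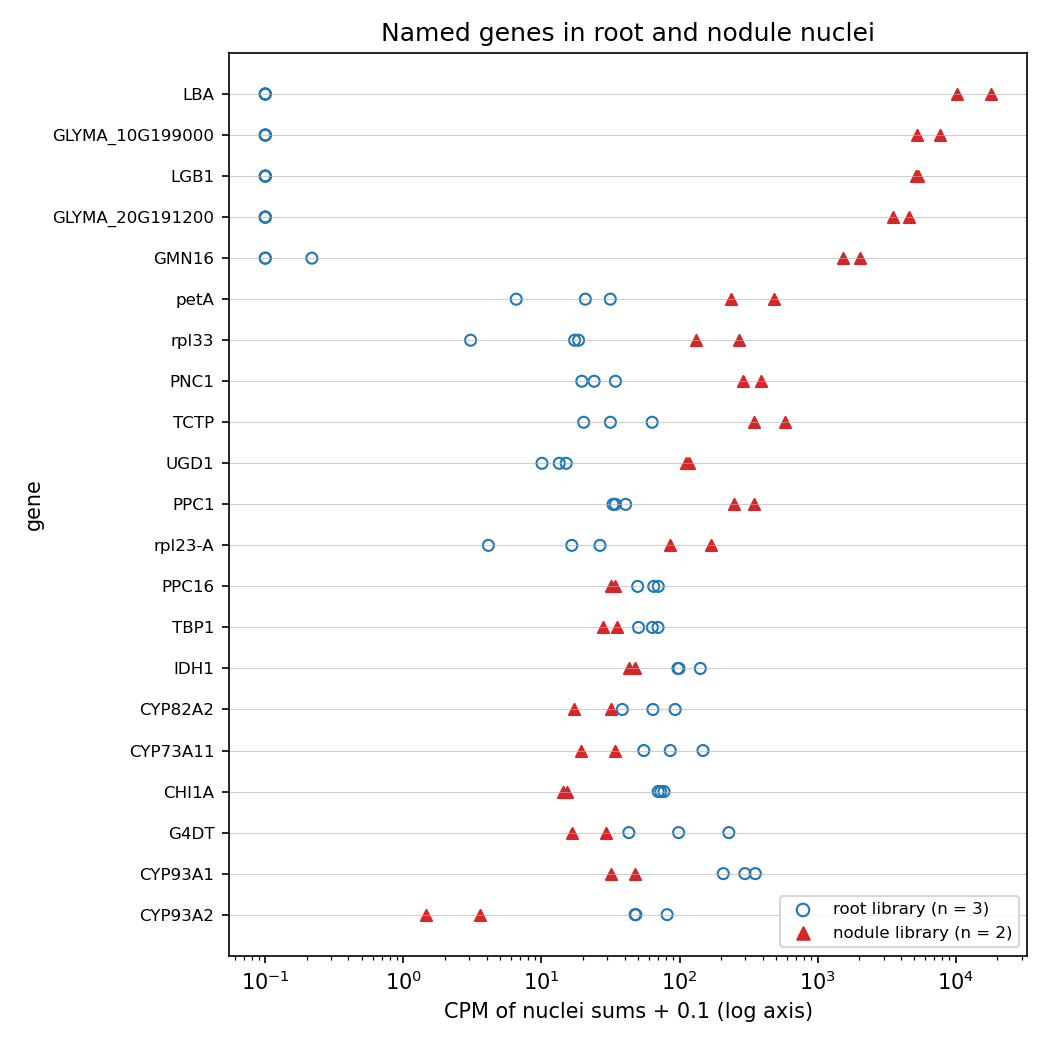
CPM of the highest and lowest named genes and the leghemoglobins in each library (log axis, 0.1 added), with root libraries as open circles (n = 3) and nodule libraries as filled triangles (n = 2). LBA stands at 0 in the root libraries and at 18060 and 10230 CPM in the nodule libraries.

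The second comparison asked which nodule nuclei carry the markers of infected cells. Infected-like nuclei made up 12.3% of nodule library 1 (95% exact binomial interval 11.7 to 12.9) and 23.8% of library 2 (22.2 to 25.4), 18.03% ± 8.10 (SD, n = 2). They held 13.2 and 32.3 UMIs of GLYMA_08G120100 per nucleus in libraries 1 and 2, against 3.68 and 5.23 in the other unnamed nuclei. In CPM it stood at 5015 and 5375 against 3272 and 2322, but was higher still in a leghemoglobin-rich cluster that was not named, at 5483 and 5964, and in plateau barcodes, at 5682 and 6455. Its CPM therefore did not rise above that of plateau barcodes. Since it was a marker of the naming rule, its excess over the other unnamed nuclei was partly built in. GLYMA_02G311000 of the Nod factor list stood at 178.8 and 218.3 CPM against 55.6 and 51.4. PNC1 was lower in them, at 85.8 and 36.1 CPM against 424.4 and 441.9, and so was PPC1, at 130.8 and 73.0 against 336.5 and 335.3.

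Leghemoglobins did not mark these nuclei by their share of UMIs. They took 1.70% and 1.19% of UMIs in infected-like nuclei, 2.38% and 1.80% in the other unnamed nuclei, 5.39% and 8.73% in the leghemoglobin-rich cluster and 4.14% and 5.29% in plateau barcodes. The name rests on proportions: LGB1 over LBA was 0.454 and 0.685 in infected-like nuclei and 0.271 and 0.400 in plateau barcodes, and GLYMA_08G120100 over LBA was 0.674 and 1.2 against 0.264 and 0.259. After thinning to 700 UMIs, 96.6% and 97.7% of infected-like nuclei held a UMI of GLYMA_08G120100, against 88.1% and 76.1% of the other unnamed nuclei. Without thinning the shares were 99.8% and 100% against 95.7% and 97.5%, at median depths of 2249 and 5381 UMIs against 1000 and 1885. Nearly all nuclei of both classes held a UMI, so this share alone does not separate expression from free RNA. The class joined cluster 8, of 1222 and 656 nuclei, and cluster 12, of 58 and 8 nuclei, whose naming rests on nodule library 1 alone. Kept outside the class were a cluster rich in leghemoglobin, with 25.2% and 8.01% of nuclei, and a cluster of 19 and 46 nuclei, with 0.183% and 1.65%.

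The share depended on which barcodes were taken as nuclei: it was 63.8% with the UMI minimum doubled and 2.50% with a fixed minimum of 500 UMIs. The rule that names the class was chosen after seeing the data. Over 20 other random seeds that rule gave between 22.9% and 23.8% of nodule library 2, but a stricter rule, with 10 nuclei asked for in every library, gave between 4.01% and 23.4%, and under 10% for 8 of the 20 seeds. The binomial intervals hold none of this.

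**Figure D2:**
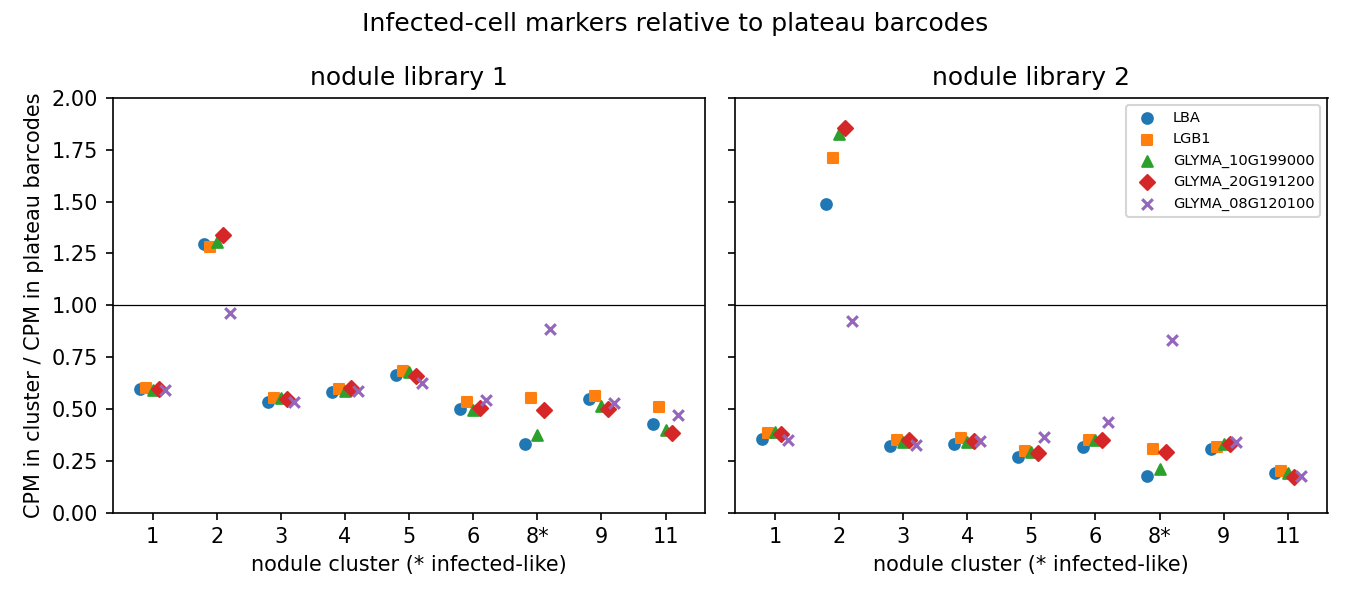
CPM of the 5 infected-cell markers in each nodule cluster of at least 40 nuclei per library, divided by their CPM in plateau barcodes, for both nodule libraries; the asterisk marks the infected-like cluster of that size. In that cluster the markers stand at unequal ratios to the plateau, with LBA lowest.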

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

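Of the tests in this part, the one on shared barcodes was set before its result was seen, and those on seed-derived free RNA and on transcription in nuclei after. Barcodes of 1 to 50 UMIs held seed transcripts in both nodule libraries. They enter the tissue comparison only in alternatives: the sums over every barcode, and the free RNA subtraction that uses the profile of empty droplets. The nodule profiles subtracted there thus held these transcripts too. A set of 159 genes, 5 of them named, was defined from these barcodes as those at over 20 times their plateau level. It took 9.33% of their UMIs in nodule 1 and 8.70% in nodule 2, against 0.121%, 0.191% and 0.235% in the root libraries. The unnamed genes of the set in these barcodes could not be called seed transcripts by name. Glycinin GY1 had 25317 counts there in nodule 1 and 23779 in nodule 2, and 0 in each root library. In root 3 the same kind of barcode held 6 counts of LBA.

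Molecules of another library read under the indexes of these libraries may account for the seed transcripts. Barcodes with a GY1 UMI in both nodule libraries were 5.08 times as frequent as chance, 3972 against 782.5, only just over the bound of 5 set in advance; the figure was 4.89 for LE1 and 1.63 for LBA. Seed-derived free RNA in the suspension would reach plateau barcodes too, but the share of GY1 was at least 748 times lower there. Transcription in nodule nuclei would put GY1 in called nuclei, where its share was at least 1980 times lower. No library of seeds was among the samples, and none was analysed here, so the origin stays a hypothesis.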

How the results depend on the processing

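Chosen after seeing the data were the random seeds, the stricter naming rule, the crossed block, the top doublet scores, the plateau-level subtraction, and the doubled minimum for lists. Of 1548 values of named genes under alternatives, 1429 kept their direction and side of the threshold, 80 lost and 38 gained a call, and 1 reversed: the log2 fold change of PRP3, 0.69 over every barcode, where the cause was not tested. Leaving out 1 library gave between 7638 and 15099 calls, 4272 to 7533 higher and 3122 to 7566 lower; the low ends came without a nodule library, which leaves 1 nodule sample assumed to vary like the roots. With all 5 libraries, alternatives gave 13379 to 20142 calls. The median shift per gene from the main log2 fold change was 0.125 with 500 UMIs, 0.126 over every barcode and -0.116 with the doubled minimum. The median log2 fold change of all genes, -0.07 in the main fit, was -0.049, -0.036 and -0.105 there. Of the lists, 3 passed by camera, 0 with an estimated correlation and 7 by fry, which asks another question. Nod factor signalling (fry adjusted p = 0.0151), carbon and nitrogen metabolism (0.00241) and lipid synthesis (0.000821) passed by fry, upward, but not by camera. Phenylpropanoid and isoflavonoid synthesis did so downward (fry adjusted p = 0.0133). Phytoalexin and defence (fry adjusted p = 0.0837) and seed and vegetative storage (0.0682) passed by neither.

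The infected-like share, 18.03%, became 63.8% with the doubled UMI minimum and 2.50% with 500 UMIs, since these change which barcodes count as nuclei. It lay between 11.6% and 25.98% with 1 nodule library left out, and between 17.27% and 18.08% over 20 other seeds. With the stricter naming rule it lay between 7.56% and 17.46% over those seeds, because a cluster mostly of nodule 2 split off and had too few nuclei in nodule 1 to be named.

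The replicate numbers were not shown to pair the samples: differences between libraries 1 and 2 correlated at -0.163 across genes. Both blocked fits used libraries 1 and 2 of each tissue, without root 3: the replicate block gave 13113 calls and the crossed block 16230, against 14539 without root 3 and no block. Under the replicate block the Nod factor list passed camera (adjusted p = 0.0405). With no block it did not, at 0.0554 without root 3 and 0.135 with all 5 libraries. Nor did it pass camera with an estimated correlation over all 5 libraries (0.558). Shares between tissues, the tissue effect within a class and its difference between classes were not run, since no class was named in both tissues.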

Other observations

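All tests in this part were chosen after the result was seen, except the one on the depth of infected-like nuclei. Among the 17 root clusters, G4DT, CYP82A2 and CYP93A1, picked after their levels were seen, were highest in cluster 7, which held 6.36%, 8.70% and 10.2% of the nuclei of root libraries 1 to 3. There G4DT stood at 716.7 ± 356.9 CPM (SD, n = 3) against a median of 69.0 over the other clusters, CYP82A2 at 441.4 ± 144.2 against 40.2, and CYP93A1 in the same cluster was highest in all 3 libraries. These 3 genes shared their highest cluster for 18 of 20 other random seeds. Others of the phytoalexin and defence list, such as CYP82A3 and PRP1, were highest elsewhere, and cluster 7 was also highest for SUBI-1 copies, IDH1 and PPC16, so no fixed list stands behind this grouping. The plastid-type genes petA, rpl33 and rpl23-A, picked likewise, shared theirs for 14 of 20, while petG and psbN were highest elsewhere. In nodules CYP93A1 was highest in cluster 4, at 158.3 ± 25.3 CPM (SD, n = 2) against 19.8, and shared it with CYP82A2 for 20 of 20 seeds, while the mean of G4DT was highest in cluster 3. Clusters were formed from expression, so no test between them was made.

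Leghemoglobin UMIs stood in every large nodule cluster. Over the unnamed clusters of at least 100 nuclei, the median of the largest over the smallest marker ratio to the plateau was 1.11 at most. The naming rule had taken out clusters where most markers beside LBA stood 1.2 times above the level that LBA and the plateau give. A low median was thus partly built in, and it cannot decide whether free RNA of the suspension accounts for these UMIs. Over 20 other seeds the median ran from 1.03 to 1.10 in nodule 1 and from 1.11 to 1.25 in nodule 2. The top of the latter range passed the bound of 1.2 that the test had set. Transcription in those nuclei stays open. From the shallowest to the deepest nuclei leghemoglobin UMIs grew 1.5 times against 2.11 for all UMIs in nodule 1, and 1.45 against 2.35 in nodule 2. This goes against transcription but not by enough to exclude it. Over 20 other seeds the first growth over the second ran from 0.66 to 0.75 in nodule 1 and from 0.62 to 0.97 in nodule 2. At the top of its range nodule 2 does not go against transcription. The leghemoglobin-rich cluster stood apart by its markers. Leghemoglobins took 5.39% and 8.73% of its UMIs against 4.14% and 5.29% in plateau barcodes, and the largest over smallest ratio was 1.39 and 2.01. The ratio of nodule 1 lay between the bounds of 1.2 and 1.5, so free RNA is left open there. Over all genes, its log CPM correlated with that of the plateau at 0.989 and 0.948. These were the highest values of any cluster, beside 0.981 and 0.946 for cluster 1. In nodule 1 its median of 862 UMIs was the lowest of the clusters, while in nodule 2 it was 2051. That cluster was picked for LBA above the plateau and ranged from 0% to 30.3% of nodule 1 over those seeds.

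In infected-like nuclei the markers departed from the plateau's proportions. Free RNA alone would hold them at 1 ratio, if the plateau gives its proportions. The largest ratio was at least 2.56 times the smallest. Depth of those nuclei would leave GLYMA_08G120100 over LBA alike among nuclei of the same UMI range, but it was at least 3.01 times higher. Over 20 other seeds that value lay between 2.91 and 3.15, and with the stricter naming rule between 1.56 and 3.43. The class was picked by these proportions, so transcription of the markers in infected cells is a hypothesis that may hold, not a finding.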
